A study of Escherichia coli with 6 samples.

How the data were processed

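RNA was measured by sequencing in 6 libraries of Escherichia coli K-12 MG1655, with 2 libraries each from the wild type, a strain labelled Δfis and a strain labelled Δhns. Per the labels, the cultures were grown with aeration in M9 minimal medium with glucose and harvested in mid-exponential phase, and the design text calls the libraries of a group biological duplicates. Total RNA was extracted with a column kit and made into cDNA libraries for Illumina sequencing. A step that depletes rRNA or removes DNA, the strandedness of the libraries, the aligner, the genome build and the annotation are not given in the sources used here.

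Per the submitters' processing notes, the authors used Cufflinks 2.2.1 and Cuffdiff 2.2.1. The deposited data are 2 tables, each comparing one mutant with the wild type over 3830 loci. Per the file headers, each table holds for every locus 1 value for the wild type and 1 for the mutant, which in Cuffdiff's layout are FPKM (fragment counts scaled by locus length and library size), so that the authors had combined the 2 libraries of a group. The deposited log2 fold change is the mutant over the wild type, and it differed by at most 1.29e-05 from the value recomputed from both FPKM columns. Also deposited are a signed test statistic (a score), a p-value and a q-value from Cuffdiff. The smallest p in the authors' deposited table was 5e-05 for either mutant. The q-value was checked to be the Benjamini-Hochberg adjustment over the loci with status OK, with a largest gap of 5.19e-07.

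No count per library was used here, so depth per library is unknown, and the spread between replicates could not be checked. No own test of a gene was therefore run. A gene was called when its status was OK and its q was at most 0.05, as fixed before the data were examined for the case of 1 FPKM per group. Loci with status NOTEST (too little signal for the authors' test) or HIDATA (too much) entered no comparison. Folds and log2 fold changes were computed from the FPKM with no pseudocount, and loci listed at 0 in a group were given no fold. An implied standard error was taken as the log2 fold change divided by the authors' test statistic. The wild-type FPKM were higher in the Δfis table than in the Δhns table by a median factor of 1.47, with a range of 1.44 to 1.49 over 3590 loci. The tables were thus normalised separately, and each mutant was compared with the wild type of its own table.

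Of the loci, 454 name several genes. Their FPKM grow with the number of names, with a median of 121 for 1 name and 238 for 2 names in Δfis, so that such loci hold sums over neighbouring genes. A locus counted once in a gene list if any of its names was in it. Coordinates are those of the deposited tables on their single chromosome, written from 1, on a build that they do not name. The RefSeq gene table of assembly ASM584v2 was used for names and synonyms only, and 4395 of 4408 distinct gene names and 1098 of 1100 list names matched it. Near-identical paralogs, such as gadA with gadB, tufA with tufB and the copies of the rRNA genes, share reads, so their separate values are uncertain. Genes that overlap an antisense RNA, such as ryeA, are uncertain as well.

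The 34 gene lists were fixed before the data were examined. Each was tested by a two-sided Fisher's exact test, per direction, of called against other tested loci, with Benjamini-Hochberg adjustment over lists and directions within a comparison. Genes of one operon are not independent, so these p-values describe these libraries. The median log2 fold change of a list was placed among 10000 random lists of the same size, matched on mean FPKM in 10 bins. This mean was taken over wild type and mutant, so the matching does not hold the wild-type level fixed. Genes were named by a rule fixed beforehand. It took all nucleoid proteins, the 10 largest rises and falls per mutant among called genes with at least 10 FPKM in the higher group, up to 4 called members of each enriched list and up to 2 of any other. Genes named outside the rule were chosen after their values were seen and are marked so.

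Both comparisons share the wild-type libraries. The correlation of their fold changes was therefore set beside 100 simulated pairs of unchanged groups drawn from the implied standard errors, and the overlap of calls beside the number that independent lists would share. Trends along the chromosome were computed over 2431 loci that name 1 gene, are at least 500 bp long and hold no rRNA. The replication origin was placed between mnmG and mioC, and each correlation was compared with 2431 rotations of the values along the chromosome.

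The alternatives were a q of at most 0.01, a change of at least 2-fold, filters at 1 and 10 FPKM with the adjustment recomputed, a pseudocount of 1, centring on the median fold change and a list background of at least 10 FPKM. Added after the data were seen were loci that name 1 gene and loci of at least 500 bp. The calling step was tested on simulated data with known changes, drawn from the implied standard errors. At a log2 change of 2, 93.3% of changed loci were called in the simulation of the Δfis table (3576 loci) and 13.3% in that of the Δhns table (3582 loci). At a log2 change of 4, these shares were 98.8% and 72.5%. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. GC content was not analysed here, since no genome sequence was used.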

Results

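Transcript levels were compared between wild-type E. coli K-12 MG1655 and strains labelled as lacking Fis or H-NS, both abundant proteins that bend or coat the bacterial chromosome and regulate many promoters. Each group had 2 libraries, and the deposited values are 1 FPKM per gene and group, so no SD or n stands beside a level. Calls are those of the authors' deposited tables at a q of at most 0.05. The series title gives the purpose as rebuilding the regulatory networks of both proteins from genome-wide data, and each labelled strain was compared with the same wild-type libraries.

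The deleted genes were examined first. In the Δhns table, hns (position 1292509 to 1292922) stood at 258 FPKM in the wild type and 2.71 FPKM in Δhns, 95.3-fold lower, although the authors' deposited table gives q = 0.136 and no call. In the Δfis table, fis (3411271 to 3411567) stood at 219 FPKM in the wild type and 111 FPKM in the libraries labelled Δfis, 1.96-fold lower, with q = 0.0435 in the authors' deposited table. The level of fis in these libraries was thus 51.0% of wild type and lay at percentile 73.3 of the 439 loci of 200 to 400 bp. This goes against the label of a deletion, and whether the deposited interval of fis lies inside the deleted part is not given in the sources used here. The group is therefore called the libraries labelled Δfis, and every direction drawn from it rests on that label.

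In Δhns, genes of acid resistance and of curli, the amyloid fibres of the biofilm matrix, rose most clearly. The glutamate-dependent acid resistance regulator gadE (3658366 to 3658893) rose 59.8-fold, from 38.4 to 2297 FPKM, and slp (3653961 to 3654527), an outer membrane lipoprotein of the same chromosomal acid fitness region, rose 79.3-fold, from 181 to 14383 FPKM. The curli master regulator csgD (1102546 to 1103196) rose 12.3-fold, from 36.2 to 443 FPKM. The H-NS paralog stpA (2798091 to 2798495) rose 9.39-fold, from 70.3 to 660 FPKM, with q = 0.009975 in the authors' deposited table. No gene was called lower.

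Of 3591 loci tested in the Δhns table, 87 were called by Cuffdiff (2.42%), and all 87 were higher in Δhns. At an unadjusted p under 0.05, the authors' deposited table holds 375 loci higher and 14 lower. The smallest rise called was 4.45-fold and the median called rise 8.61-fold, and the median implied standard error was 0.95 on the log2 scale. The median level over the called loci was 41.5 FPKM in the wild type and 443 FPKM in Δhns. Of the 87 loci, 48 lay in the lowest of 10 bins of wild-type level, which reached up to 54.6 FPKM. A q of at most 0.01 left 18 calls, and a restriction to loci of at least 500 bp, chosen after seeing the data, left 32.

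**Figure D1:**
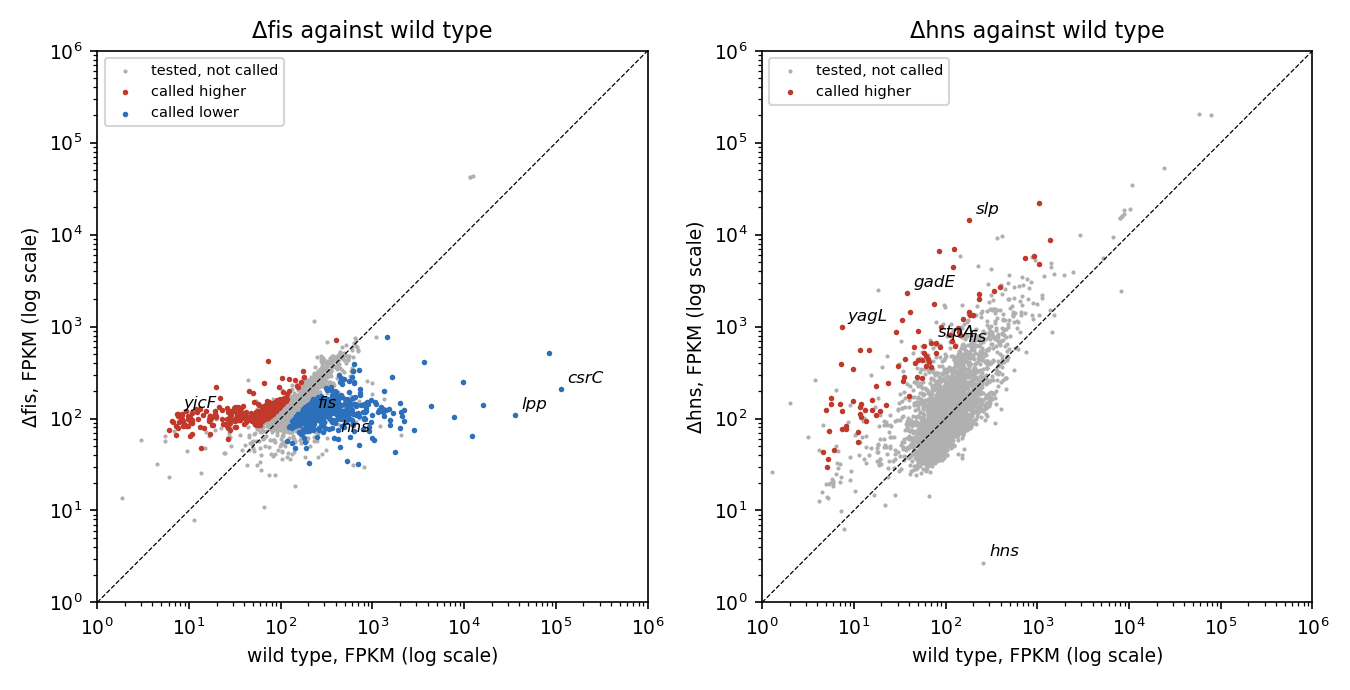
FPKM of each tested locus in the mutant (vertical, log scale) against wild type (horizontal, log scale), left for the libraries labelled Δfis and right for Δhns; each point is 1 locus, red called higher and blue called lower, the dashed line marks equal values, and the 9 tested loci per table listed at 0 in a group (1 of the 87 calls in Δhns, 3 of the 829 in the libraries labelled Δfis) are not drawn. In Δhns all drawn calls lie above the line, whereas the called loci of the libraries labelled Δfis lie in a flat band, with medians of 116 FPKM for those called higher and 117 FPKM for those called lower.

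The largest called rise in Δhns was that of yagL, a gene of the CP4-6 prophage, at 133-fold (7.37 to 980 FPKM). It was followed by slp, by ydeI at 76.7-fold and by gadE. The glutamate decarboxylase genes gadA and gadB rose 57.1-fold and 36.3-fold, values that are uncertain for each copy because the genes are nearly identical. The other large rises were ybbC (53.4-fold), yegR (47.5-fold), yibB (37.8-fold) and yciE (35.4-fold). For these 10 genes q in the authors' deposited table lay between 0.009975 for slp and yciE and 0.0387 for yibB.

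Among the acid resistance genes, 8 of 18 tested loci were called higher in Δhns and none lower, an enrichment with an exact-test adjusted p = 2.1e-07 by Fisher's test, and 14 were called higher when adjusted over the list alone. Their median log2 fold change was 3.46, higher than in all 10000 matched random lists. At a q of at most 0.01 this enrichment was lost (exact-test adjusted p = 1). Curli genes were called higher at 5 of 7 loci (exact-test adjusted p = 5.12e-06) and at 6 adjusted over the list alone, with a median log2 fold change of 2.90. Besides csgD, these included csgE, at 10.3-fold, csgB, which encodes the nucleator subunit, at 7.99-fold, and csgF at 7.45-fold.

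Cryptic prophage genes were enriched among the rises in Δhns with 10 of 134 loci called (exact-test adjusted p = 0.0292) and 14 adjusted over the list alone, and the enrichment was lost at a q of at most 0.01 (exact-test adjusted p = 0.467). The median of this list was −0.14, opposite in sign to its test, as 75 of its loci lay below wild type and none of these was called. Its called members included yagM at 25.5-fold, ybcK at 12.1-fold and yfjJ at 11.5-fold.

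Several other groups held called members in Δhns without enrichment. In the general stress list of RpoS-dependent genes, 3 of 31 loci were called higher (exact-test adjusted p = 0.644) and 17 adjusted over the list alone, with yciF at 18.1-fold beside yciE, and a median log2 fold change of 1.67. Nucleoid proteins had 2 of 17 loci called higher (exact-test adjusted p = 0.848), stpA and the integration host factor gene ihfB at 8.60-fold. Adjusted over the list alone, 10 nucleoid protein loci were higher and 1, hns, was lower. The nucleoid genes without a call included fis at 588 FPKM against 149 in the wild type (q = 0.126 in the authors' deposited table), and the starvation protein gene dps at 4270 against 317 FPKM (q = 0.196 in the authors' deposited table). The gene of the H-NS partner Hha stood at 519 against 44.2 FPKM (q = 0.132 in the authors' deposited table).

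Chaperone-usher fimbriae had 2 of 45 loci called higher in Δhns (4 adjusted over the list alone), elfA with a log2 fold change of 3.70 and yehA at 6.25-fold. One call each came from CRISPR-Cas (the locus of casD and casE at 4.83-fold; 3 of 6 loci adjusted over the list alone), LPS core synthesis (waaL, the O-antigen ligase, at 5.04-fold) and the bgl and proU operons (bglG, the antiterminator of the cryptic bgl operon, at 4.93-fold). One call each also came from heat shock (the cochaperonin gene groS at 6.26-fold) and multidrug efflux (the response regulator gene evgA at 8.61-fold), and each of these last 4 lists kept 1 call adjusted over the list alone. Ribosomal proteins had 2 of 49 loci called higher, including rpmB at 7.69-fold and rpmF. The latter was listed at 0 in the wild type, which need not be an absence, and at 508 FPKM in Δhns. It was named here after its value was seen. Adjusted over the list alone, 7 ribosomal protein loci were higher. All 49 lay above wild type, with a median log2 fold change of 1.28, and 17 were higher at an unadjusted p under 0.05 in Cuffdiff. None of these lists was enriched among the rises (exact-test adjusted p = 1 for each). Against matched random lists, the medians of fimbriae, RpoS-dependent, LPS core, CRISPR-Cas and heat shock genes lay at percentiles 100, 99.99, 99.97, 98.6 and 97.4. Those of nucleoid proteins, the bgl and proU operons, multidrug efflux and ribosomal proteins lay at 89.2, 78.0, 53.3 and 19.7. The matching does not hold the wild-type level fixed.

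Flagellar genes were not called in Δhns (0 of 29), also adjusted over the list alone. At 26 of these 29 loci the level was below wild type, with a median log2 fold change of −0.80 that was lower than in all 10000 matched random lists. The 14 motility and chemotaxis loci had a median of −0.83, all below wild type, and the 31 iron uptake loci a median of −0.75, with 26 below wild type, and none was called, also adjusted over the list alone. The median was −0.62 for the 15 TCA cycle loci, −0.42 for the 27 anaerobic respiration loci, −0.26 for the 83 loci of alternative carbon sources and 0.06 for the 24 loci of aerobic respiration and ATP synthase. For biosynthesis, medians were 1.53 for arginine, 1.20 for histidine, 0.16 for branched-chain and 0.24 for aromatic amino acids, −0.50 for methionine, −0.29 for cysteine and sulfate assimilation and −0.51 for purines and pyrimidines. Glycolysis and the pentose phosphate path had a median of 1.07, translation factors and tRNA synthetases 0.75, the 7 rRNA loci 0.94, SOS genes 0.26, O antigen and colanic acid 0.34, type II secretion −0.27 and topoisomerases −0.01 (0.01 after centring). No locus of these lists was called in either direction, also adjusted over the list alone, and tRNA genes had no tested locus in either table. At an unadjusted p under 0.05 in Cuffdiff, flagellar, motility and iron uptake genes held 0 loci in either direction, O antigen and colanic acid 5 higher, glycolysis 3 higher, and alternative carbon sources 1 higher and 3 lower. Translation factors, SOS genes and the histidine, arginine and aromatic pathways held 1 higher each, and the other lists of this group 0. At single loci of these lists, changes of this size were not called, with the median implied standard error of Δhns. As lists, the medians of iron uptake, anaerobic respiration, the TCA cycle, aerobic respiration, alternative carbon sources and motility lay at percentiles 0, 0.01, 0.02, 0.19, 0.3 and 0.35 of their matched random lists. Flagellar, motility and iron uptake loci had median wild-type levels of 67.6, 66.7 and 81.0 FPKM. Tested loci of like level also lay lower in Δhns. In bins 3 and 5 of 10 by wild-type level, medians went from 69.6 to 55.0 FPKM and from 84.4 to 64.3 FPKM. In the highest bin the median went from 314 to 527 FPKM. The medians of these 3 lists were not separated from this shift.

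**Figure D2:**
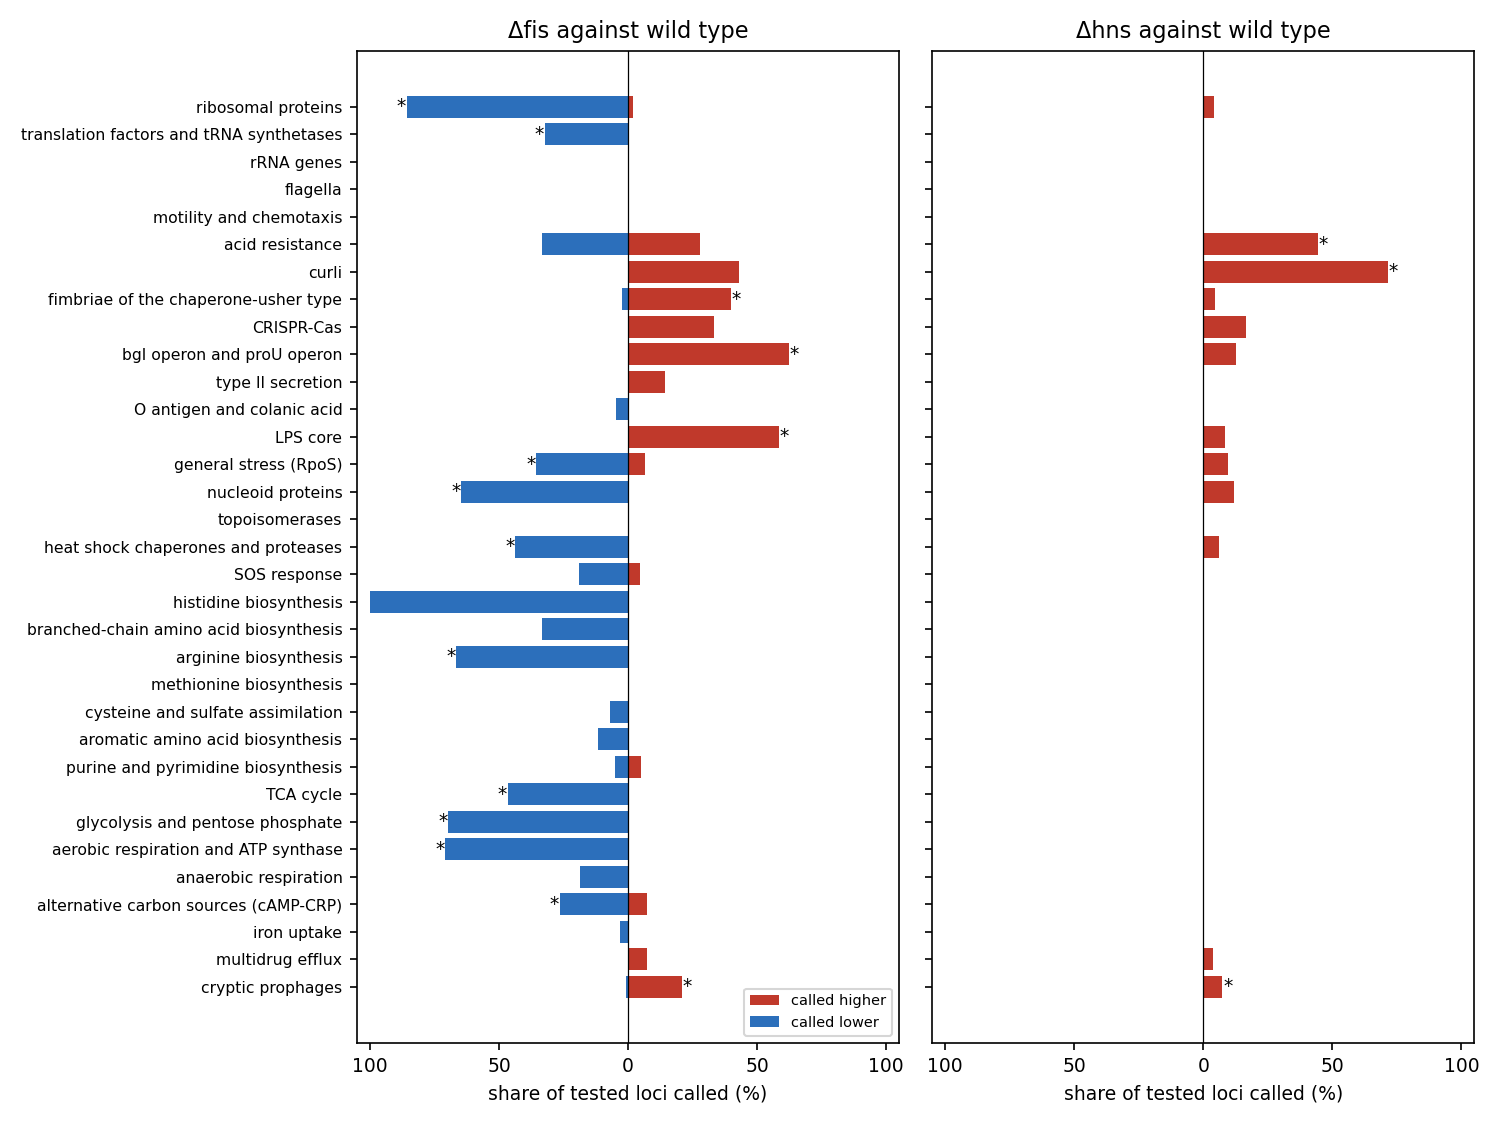
Share of each gene list's tested loci (horizontal, %) that was called higher (red, to the right) or lower (blue, to the left), left for the libraries labelled Δfis and right for Δhns; asterisks mark lists with an adjusted p of at most 0.05 and a share above that of the other loci, and the list without a tested locus is left out. Acid resistance (8 of 18) and curli (5 of 7) stand out in Δhns, and ribosomal proteins (42 of 49 lower) in the libraries labelled Δfis.

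In the libraries labelled Δfis, the most abundant transcripts of the wild type were far lower and the least abundant were higher. The small regulatory RNA csrC (4051036 to 4051280), which sequesters the translational regulator CsrA, fell 550-fold, from 114397 to 208 FPKM, and lpp (1757421 to 1757657), the gene of the major outer membrane lipoprotein, fell 325-fold, from 35703 to 110 FPKM. Ribosomal proteins were called lower at 42 of 49 loci, and glycolytic, aerobic respiration and nucleoid protein genes were called lower at most of their loci. Genes called higher included fimbrial, prophage, LPS core and bgl genes. The rRNA genes rrsA, rrsB and rrsE lay between 41877 and 43831 FPKM, against 11691 to 12445 in the wild type, and were not called; they were named after their values were seen.

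Of 3585 loci tested in the Δfis table, 829 were called by Cuffdiff (23.1%), 309 higher and 520 lower. The median called change was 2.09-fold and the median implied standard error 0.28 on the log2 scale. With a change of at least 2-fold required, 138 rises and 306 falls remained. Among loci of at least 500 bp, a choice made after seeing the data, 306 were called lower. Levels in these libraries lay close together: over the 2431 long loci naming 1 gene, 99.3% were within 2-fold of the median, against 87.7% in the wild type and 72.2% in Δhns, and the SD of log2 FPKM was 0.30, 0.83 and 1.23. The direction of a call followed the wild-type level, as 217 of 358 loci in the lowest of 10 bins of that level were called higher and 0 lower, and 209 of 358 in the highest bin were called lower and 1 higher.

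Level also followed position on the chromosome in the libraries labelled Δfis. The correlation of FPKM with distance from the replication origin across these 2431 loci, which are not independent replicates, was rho = −0.82, and a share of 0.00535 of rotations was as low. It was −0.42 in the wild type (0.00617 of rotations) and −0.04 in Δhns (0.051 of rotations). With the loci split by distance into 5 bins, the median of the nearest bin was 154 FPKM in the libraries labelled Δfis and that of the farthest 101 FPKM, a ratio of 1.53. The ratio was 1.49 in the wild type and 1.06 in Δhns.

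**Figure D3:**
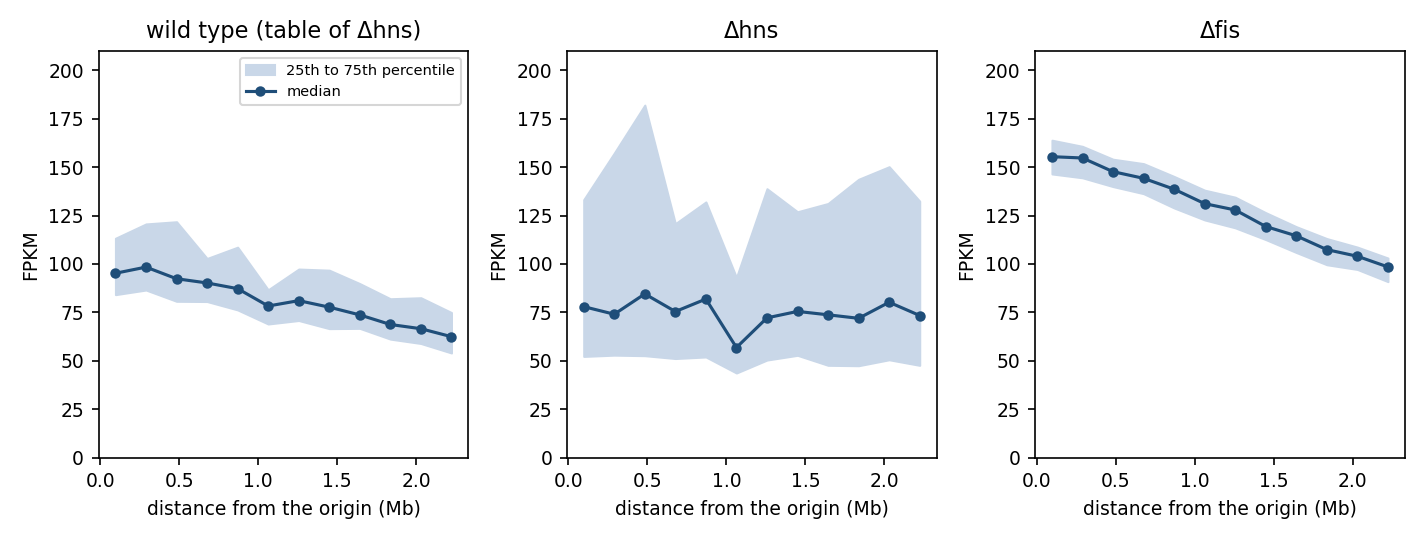
FPKM (vertical) against distance from the replication origin in Mb (horizontal) for the wild type of the Δhns table, Δhns and the libraries labelled Δfis, over 2431 loci; lines join the medians of bins of equal width and the shaded band spans the 25th to 75th percentile of loci. The median falls from 154 FPKM in the nearest of 5 groups of loci to 101 FPKM in the farthest in the libraries labelled Δfis, with a narrow band, and goes from 81.3 to 76.6 FPKM in Δhns.

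After csrC and lpp, the largest called falls in the libraries labelled Δfis were those of ryeA (187-fold), csrB (166-fold), the tmRNA gene ssrA (116-fold), the ribosome hibernation gene raiA (74.5-fold) and yeaQ (41.0-fold). They were followed by the 6S RNA gene ssrS (39.6-fold), the cold shock family gene cspE (38.4-fold) and the RNase P RNA gene rnpB (31.3-fold). These 10 genes ended between 42.7 FPKM for yeaQ and 512 FPKM for csrB. The largest called rises were yjcF (15.1-fold), yjbI (15.0-fold), yrhC (14.4-fold), ypjC (14.2-fold), yibG (13.9-fold), yccE (13.6-fold), yagM (13.3-fold), yigF (13.2-fold), ygeH (12.9-fold) and yddK (12.2-fold). These 10 went from 6.07 to 9.32 FPKM in the wild type to 74.3 to 120 FPKM. For 9 of them, all but yrhC (q = 0.00499), q was 0.000423, the smallest in the authors' deposited table.

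The direction of a call in the libraries labelled Δfis followed wild-type level. Lists of highly expressed genes would thus tend to appear among the falls, and lists of weakly expressed genes among the rises. The list tests below do not separate this from a change particular to a list. Genes of the translation machinery were called lower in the libraries labelled Δfis. Ribosomal protein loci went from a median of 502 FPKM to 129 FPKM, with an exact-test adjusted p of 3.06e-27 for the 42 lower calls (43 adjusted over the list alone). There was 1 locus, rpmF, called higher from a listed 0 that need not be an absence, and it was named after its value was seen. Examples of the falls are rpsU at 13.7-fold lower, the locus of rplP, rpmC and rpsQ at 8.81-fold lower, rplO at 7.66-fold lower and rpmB at 7.17-fold lower. Translation factors and tRNA synthetases fell at 11 of 34 loci (exact-test adjusted p = 0.0294; 11 adjusted over the list alone), with infC at 10.3-fold lower and tsf at 5.37-fold lower. The elongation factor Tu copies tufA and tufB were 6.62-fold and 3.78-fold lower and share reads. The enrichment of this list was lost at 2-fold (exact-test adjusted p = 0.323) and at a q of at most 0.01 (exact-test adjusted p = 0.662).

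Lists of glycolysis, aerobic respiration, the TCA cycle and alternative carbon sources were also enriched among the falls in the libraries labelled Δfis. Glycolysis and the pentose phosphate path fell at 16 of 23 loci (exact-test adjusted p = 6.45e-08; 19 adjusted over the list alone), including eno at 5.58-fold, crr at 5.37-fold, gapA at 4.56-fold and fbaA at 3.68-fold. Aerobic respiration and ATP synthase fell at 17 of 24 loci (exact-test adjusted p = 1.92e-08; 20 adjusted over the list alone), including atpE at 5.63-fold, cydA at 4.02-fold, atpA at 3.78-fold and atpD at 3.71-fold. The TCA cycle fell at 7 of 15 loci (exact-test adjusted p = 0.0164; 8 adjusted over the list alone), including mdh at 2.59-fold, aceA at 2.42-fold, aceB at 2.36-fold and fumA at 2.31-fold. Alternative carbon sources fell at 22 of 83 loci (exact-test adjusted p = 0.0204; 23 adjusted over the list alone) and rose at 6, and the falls were led by galactitol genes, gatY at 23.8-fold, gatB at 16.0-fold, gatZ at 14.6-fold and gatC at 9.02-fold. Median levels of the first 3 of these lists in the libraries labelled Δfis were 124, 132 and 135 FPKM, against 242, 302 and 230 FPKM in the wild type. Among random lists matched on mean FPKM, the median log2 fold change lay at percentile 0.975 for glycolysis, 1.18 for aerobic respiration, 4.35 for the TCA cycle and 36.9 for alternative carbon sources, whose median was −0.09. For the translation machinery these percentiles were 0 for ribosomal proteins and 7.15 for translation factors and tRNA synthetases. The mean used for matching includes the mutant value, and its highest bin has no upper limit. These percentiles therefore do not remove the effect of wild-type level.

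Nucleoid proteins fell at 11 of 17 loci in the libraries labelled Δfis (exact-test adjusted p = 3.31e-05; 13 adjusted over the list alone). The HU subunit genes hupA and hupB were 6.91-fold and 4.18-fold lower, hns 6.15-fold, dps 4.53-fold, ihfB 4.37-fold, ihfA 4.14-fold, hfq 2.62-fold, slyA 2.46-fold and lrp 1.57-fold. The gene cnu was listed at 0 FPKM against 45.7 in the wild type, and fis itself is given above. Whether the 0 of cnu is an absence or a failed estimate is unknown. Not called were stpA (88.0 against 103 FPKM), hha, dnaA, seqA and the loci of cbpA and mukB. RpoS-dependent genes fell at 11 of 31 loci (exact-test adjusted p = 0.0164; 11 adjusted over the list alone) and rose at 2, with elaB 6.06-fold, msyB 4.27-fold and osmC 3.30-fold lower. Heat shock genes fell at 7 of 16 loci (exact-test adjusted p = 0.0219; 7 adjusted over the list alone), including hspQ at 3.91-fold, dnaK at 2.41-fold, groL at 2.40-fold and clpP at 2.09-fold, and the enrichment was lost at 2-fold (exact-test adjusted p = 0.236) and at a q of at most 0.01 (exact-test adjusted p = 0.113). The arginine biosynthesis list, which also holds the arginine transport gene artJ, fell at 8 of 12 loci (exact-test adjusted p = 0.000407; 9 adjusted over the list alone). These included artJ at 2.53-fold, argG at 2.21-fold, argA at 2.01-fold and argB at 1.77-fold. The enrichment of this list was lost at 2-fold (exact-test adjusted p = 0.323). Among matched random lists, the medians of nucleoid proteins, heat shock, RpoS-dependent and arginine genes lay at percentiles 0.08, 2.36, 6.58 and 11.9.

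Among the rises in the libraries labelled Δfis, chaperone-usher fimbriae had 18 of 45 loci called (exact-test adjusted p = 1.44e-07; 20 adjusted over the list alone), including yadC at 3.55-fold, yehA at 3.19-fold, yehD at 3.13-fold and yadK at 2.59-fold. LPS core genes rose at 7 of 12 loci (exact-test adjusted p = 0.000152; 7 adjusted over the list alone), including waaZ at 6.34-fold, waaL at 6.09-fold, waaU at 3.78-fold and waaR at 3.42-fold. The bgl and proU operons rose at 5 of 8 loci (exact-test adjusted p = 0.00141; 5 adjusted over the list alone), with bglG at 1.78-fold, bglH at 1.59-fold, the locus of bglJ and yjjQ at 1.51-fold and bglB at 1.43-fold, and the enrichment was lost at 2-fold (exact-test adjusted p = 1). Cryptic prophages rose at 28 of 134 loci (exact-test adjusted p = 5.66e-05; 27 adjusted over the list alone) and fell at 1, a depletion of falls with an exact-test adjusted p = 3.2e-07, and the rises included yagL at 10.7-fold, ymfD at 9.33-fold and ymfE at 9.22-fold. Median levels of these lists in the libraries labelled Δfis were 118, 135, 155 and 113 FPKM, against 83.4, 111, 113 and 100 FPKM in the wild type. Their median log2 fold changes lay at percentiles 100, 99.9, 99.99 and 99.9 of matched random lists, which do not remove the effect of wild-type level either.

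The remaining lists were not enriched in either direction in the libraries labelled Δfis. Acid resistance genes split, with 5 of 18 loci higher and 6 lower and the same numbers adjusted over the list alone, and its largest changes were those of the periplasmic acid chaperone genes hdeA and hdeB, with log2 fold changes of −3.59 and −2.39. Curli genes were called higher at 3 of 7 loci (4 adjusted over the list alone), with csgE at 2.76-fold and csgF at 1.88-fold, and CRISPR-Cas at 2 of 6 (2 adjusted over the list alone), casC at 1.59-fold and ygcB at 1.56-fold. Multidrug efflux had 2 of 27 loci higher (2 adjusted over the list alone), the locus of emrK and emrY at 2.28-fold and evgS at 2.11-fold, and type II secretion 1 of 7 (1 adjusted over the list alone), gspA at 1.43-fold. Histidine biosynthesis was lower at both of its 2 loci, also adjusted over the list alone (exact-test adjusted p = 0.0714), with hisG at 2.43-fold, and branched-chain amino acid synthesis at 4 of 12 (8 adjusted over the list alone), with leuC at 2.40-fold and leuD at 2.24-fold. Anaerobic respiration was lower at 5 of 27 loci (5 adjusted over the list alone), with frdC at 4.16-fold and frdD at 2.85-fold, and SOS genes at 4 of 21 (4 adjusted over the list alone) with 1 higher, including dinJ at 3.03-fold and yebG at 2.42-fold lower.

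Single calls stood in the other lists of the Δfis table. They were cysK at 2.85-fold lower of 14 cysteine and sulfate loci, wzzB at 1.91-fold lower of 22 O antigen and colanic acid loci and the locus of fur and uof at 2.02-fold lower of 31 iron uptake loci, each also 1 lower call adjusted over the list alone. Aromatic amino acid synthesis had 2 of 17 loci lower (2 adjusted over the list alone), aroK at 1.62-fold and aroG at 1.52-fold. Purine and pyrimidine synthesis had purA at 1.88-fold lower and pyrD at 1.41-fold higher of 20 loci, of which 1 lower and 0 higher remained adjusted over the list alone. No call was made by Cuffdiff among 29 flagellar, 14 motility, 12 methionine and 6 topoisomerase loci or the 3 tested rRNA loci, also adjusted over the list alone. At an unadjusted p under 0.05, 1 flagellar locus was lower, 2 motility loci were higher and 2 methionine loci were lower, by Cuffdiff.

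The Δhns comparison and that of the libraries labelled Δfis were then set side by side, to ask whether the same genes were called in both. Of 3581 loci tested in both tables, 47 were called higher in both, including csgD, csgE, csgF, gadE, yagL, yagM, waaL and bglG, and independent lists of 309 and 87 loci would share 7.51. With the Δhns calls shuffled within 20 bins of wild-type level, 34.2 shared loci were expected against 46 observed among loci with a fold in both tables. A further 16, including hdeA, slp, gadB, ihfB, elaB and rpmB, were called lower in the libraries labelled Δfis and higher in Δhns, where independent lists would share 12.6. At a q of at most 0.01, 10 loci were higher in both. The examples of both kinds were picked after their values were seen. Across 3572 loci, which are not independent replicates, the log2 fold changes of both comparisons had a Spearman rho of −0.26, below the range of 0.12 to 0.21 over 100 simulated pairs of unchanged groups sharing the wild type. Pearson's r was −0.03, within the simulated range of −0.47 to 0.75, and the covariance was −0.03 against a simulated mean of 0.35. Changes followed wild-type level in both comparisons, and the simulated groups hold no such trend. The negative rho therefore does not show opposite regulation by both proteins. The wild-type libraries could not be split, so part of the shared calls may come from the shared wild type.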

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

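The tests on the level of the libraries labelled Δfis, the test of a background floor in Δhns and the count of loci with room to fall were chosen only after those results were seen, and the other 3 tests were written before theirs.

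Loci outside the authors' test carried signal in a mutant while listed at 0 in the wild type, and are named here for that reason, after their values were seen. The 23S rRNA genes rrlA, rrlB, rrlC, rrlD, rrlE, rrlG and rrlH were listed at 11986, 11331, 14233, 13580, 11330, 13793 and 11923 FPKM in the libraries labelled Δfis, with a status that marks too much data, so that the 0 of the wild type need not be an absence. In Δhns, the prophage genes intG and ydaF were listed at 80.5 and 239 FPKM, with a status that marks too little data for a test.

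FPKM in the libraries labelled Δfis lay close to one level across genes. Loss of most mRNA to rRNA reads, which would lower all other genes by one factor and keep their spread, is argued against by an SD of log2 FPKM that was 0.364 times that of the wild type. Genomic DNA in the sequenced material is a candidate explanation, because the level fell with distance from the origin (rho = −0.823) and 6 abundant RNAs (csrB, csrC, ssrA, ssrS, rnpB and lpp) lay at a median of 1.37 times the median locus, against 218 times in the wild type. DNA alone would not place rrsA at 43831 FPKM, so RNA was present as well, and DNA stays open in the wild type too, where the ratio of nearest to farthest loci was 1.49 against 1.53. An effect of losing Fis on these genes stays open and untested, since fis was at 51.0% of wild type and only these libraries carry the label. That share need not be a partial loss of fis, whose 111 FPKM lay at percentile 73.3 of loci of 200 to 400 bp. If the common level is that of DNA, the deposited interval of fis was present in that DNA.

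In Δhns, 87 loci were called higher and none lower. A position-dependent background in the wild type is argued against as the whole cause by its size. Its ratio of nearest to farthest loci was 1.49, and the smallest called rise was 4.45-fold. Called loci lay at a median distance percentile of 55.6, but so small a trend need not move that percentile, so it cannot decide. Fold changes over all 2431 loci did rise with distance (rho = 0.18, from a median log2 of −0.22 nearest the origin to 0.26 farthest), so a small contribution is not excluded. A background coverage that keeps loci from falling far may contribute, since 0.329% of 2431 loci lay below 0.25 times the median Δhns FPKM. The 2.71 FPKM of hns cannot decide on this, because a deleted gene would be missing from a DNA background as well. Of 219 loci that moved by at least the smallest called rise, 2 fell (0.913%), but a floor keeps that share low. Among 325 loci with room to stay above the 25th percentile of Δhns FPKM, 36 rose that much and 1 fell. That fall was hns, at 258 FPKM in the wild type, the gene that the label names as deleted. Among 158 with room to stay above the median, 21 rose and 0 fell. For these loci, this argues against a spread around no change that hides rises and falls alike. Relative to their own median log2 fold change of 0.80, the 325 loci gave 8 rises and 6 falls. Centring on that median favours such a balance by itself, so a spread around the raised median stays open. The loss of a repressor, as the design names it, stays open and was not tested.

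The 47 loci called higher in both comparisons had a median wild-type level of 11.9 FPKM in the Δhns table, against 88.5 FPKM over tested loci. A low wild-type level shared by both comparisons accounts for much of the overlap, with 34.2 shared loci expected within 20 bins of wild-type level against 46 observed among loci with a fold. It is argued against as the whole cause by shuffles within these bins, of which 0.02% reached the observed number, and 0.05% with 100 bins. The shuffles treat neighbouring loci such as csgD, csgE and csgF as independent and do not match locus length, so these shares may be too small. Chance values of the shared wild-type libraries remain open and could not be removed. An effect on these genes of the genotypes that the labels name stays open and untested.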

How the results depend on the processing

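The loci of at least 500 bp and the loci naming 1 gene were chosen after the data were seen. Requiring at least a 2-fold change took the rises in the libraries labelled Δfis from 309 to 138 and the falls from 520 to 306, because small changes are left out. Loci of at least 500 bp gave 306 falls there and 32 rises in Δhns, whereas the rises in the libraries labelled Δfis went only from 309 to 267. Fewer loci were tested in this setting, which alone need not account for the larger drops. A dependence of the calls on locus length was not tested. A q of at most 0.01 took the rises in Δhns from 87 to 18, its enriched lists from 3 to 1 and the rises shared by both comparisons from 47 to 10; the 18 all carry the smallest p of the table. Over these and the other settings, 44 counts stayed within 1.5 times. Of 68 repeated list tests, 60 kept their side of the threshold and 8 lost it, 4 at 2-fold and 4 at a q of at most 0.01, and 29 named genes lost their call at that q. No called value reversed. Of the 132 list medians with a pseudocount of 1 or centring, all but 2 kept their sign: centring took purine and pyrimidine synthesis in the libraries labelled Δfis from 0.03 to −0.01 and topoisomerases in Δhns from −0.01 to 0.01, both lists without enrichment. No paired analysis was possible because the tables hold 1 value per group and none per library. For the same reason, leaving out each replicate, the replicate block and the count tests were not run, and the GC tests, with their permutation and rotation, were not run without a genome sequence. Depth is unknown. In simulated data, 1.67% of 2-fold changes (log2 of 1) were called in Δhns over 3582 loci, against 66.7% in the Δfis table over 3576. The simulation used a normal p that Cuffdiff's p did not always follow, so these shares are not the power of the deposited calls. In Δhns, hns was 95.3-fold lower without a call, so a missing call there does not show that a gene was unchanged.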

Other observations

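The abundant regulatory and structural RNAs that were low in the libraries labelled Δfis stood above wild type in Δhns, without a call. The small RNAs csrB and csrC stood at 204438 and 202569 FPKM in Δhns against 57573 and 77469 FPKM in the wild type, with q = 0.64 and q = 0.686 in the authors' deposited table, and lpp at 53100 against 24224 FPKM. The 6 abundant RNAs lay at a median of 585 times the median locus in Δhns, against 216 times in the wild type compared with it. DNA stays open in that wild type. A difference in background between the groups was therefore not separated from an effect of the genotype that the label names. These genes were chosen after their values were seen in the libraries labelled Δfis.

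Genes called higher in Δhns without belonging to a list included the phage shock genes pspA and pspG, with log2 fold changes of 2.85 and 2.69, and the regulators appY, rcsA and ydeO, with 5.13, 3.70 and 3.30. In the libraries labelled Δfis, pspA and pspG were called lower, with −1.40 and −3.65, and appY, rcsA and ydeO were called higher, with 2.46, 1.78 and 1.90. These genes were chosen after their values were seen. The 8 acid resistance loci called in Δhns had a median log2 fold change of 4.87 there and 0.04 in the libraries labelled Δfis.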
